A study of sulfo-oxidizing enrichment culture with 4 samples.

How the data were processed

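Read counts per taxon were deposited for 4 samples of suspended chemostat biomass as 7 tables, from kingdom to species. Per the labels' protocols, the biomass was concentrated by centrifugation, DNA was extracted with a commercial biofilm kit, and V3-V4 amplicons of the 16S rRNA gene were prepared by Illumina's protocol and sequenced as read pairs. The read filters, the merging of pairs, the classifier and its reference database are not given in the sources used here. The values are whole numbers whose totals differ between samples and fall from kingdom to species, so the deposited counts were taken as raw read counts in which reads without a name at a level are not listed there. In 6 of the 7 deposited tables every count of sample 4A ended in a stray backslash and letter n, which was removed. All deposited tables below the kingdom level carry the same level heading, so levels were taken from the table titles and the names in them.

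Classified reads per sample were the kingdom-level totals, 82438 in 1CP, 50343 in 2CP, 59219 in 3CP and 58032 in 4A. Reads without a genus name were 0.957%, 5.39%, 2.73% and 1.83% of these, taken as the kingdom total less the genus total. A count of 0 in the genus table allows a share of up to 3 reads, which is 0.00367% in 1CP, 0.00630% in 2CP, 0.00521% in 3CP and 0.00527% in 4A. The genus table lists 859 genera, of which 533 had a read in any sample. The 16S copy number of the taxa was not corrected for, and amplification bias between taxa was not measured.

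The labels used here give no group, condition, time or replicate for the samples, and the letters in the sample names are not explained there. All 4 samples were therefore left without a group, no comparison between groups was made, and no test treated samples as replicates. No outlier test was applied for the same reason.

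The share of each genus is its reads over all reads of the genus table, with a Wilson 95% interval. Shares of phyla, classes and species names use the total of their own table. The ratio of 2 counts within a library or of 2 shares has a 95% log-normal interval. Shannon diversity was computed in natural-log units over genera with reads lacking a genus name as 1 category, and Bray-Curtis dissimilarity on relative abundances over the same categories, each with the 2.5 to 97.5 percentile of 2000 multinomial resamples of the reads. The number of genera at even depth is the mean of 200 random subsamples to 47627 reads. Pairs of libraries were compared by a chi-square test over genera with at least 10 reads in the pair, to ask whether any 2 libraries differed by no more than the sampling of reads.

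Choices made before the data were examined were the analyses above, 11 lists holding 169 genera by known metabolism or origin, matched on the exact genus name, the alternatives below, and the rule for naming taxa. The rule named phyla and classes with at least 1% of reads in a sample, at most 8 each, the 12 genera with the highest share averaged with equal weight over samples, the 8 other genera with the largest ratio of highest to lowest share among those with at least 0.5% in a sample, the 2 leading members of each list with at least 0.1% in a sample, and the 5 leading species names. It gave 4 phyla, 8 classes, 23 genera and 5 species names. List members outside the rule were named where they led their list in a sample or were its few remaining reads, and Escherichia/Shigella because its joint name kept it off a list, and genera on no list such as Thioalkalimicrobium and Fusibacter to show what the lists leave out, all chosen after their values were seen. The rows Clostridium with a cluster suffix were likewise not matched by the list name Clostridium, and held at most 8 reads each in any sample.

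The alternatives fixed in advance were a wider list of sulfur oxidisers, family and species levels, genera with at least 10 reads over all samples, reads with a genus name only, subsampling to the shallowest sample, reads without a name left out, a square-root transformation and the Jaccard measure. All classified reads as the base of shares and the sulfur-oxidising, nitrate-reducing list with Thiopseudomonas were added after the data were seen, as were the alternatives for named genera other than Thiobacillus. The genus table holds only named reads, so the base of reads with a genus name only was identical to the reported one.

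The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on 200 simulated pairs of libraries with the genera and depths of 2CP and 3CP, in which 200 genera were changed 2-fold up or down. Over 90 genera with at least 5 expected reads, the Wilson interval held the true share in 95.0% of cases and the interval of a ratio held the true ratio in 96.0%. In 100 such pairs over all 859 listed genera, the mean Shannon diversity of 200 resamples lay within 0.02 of its true value in 96%. The mean Bray-Curtis dissimilarity of 200 resamples lay within 0.01 in 100%. Whether the resampling intervals of both measures held the true value was not tested. The simulated reads were drawn independently, so error beyond counting was not tested either.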

Results

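The community of a sulfide- and nitrate-fed laboratory chemostat, started from biomass enriched for sulfur oxidation, was profiled by sequencing the V3-V4 part of the 16S rRNA gene. A chemostat is a continuously fed and drained culture. Biomass was sampled from suspension at 30 °C and pH 7.6. There were 4 samples, named 1CP, 2CP, 3CP and 4A. The labels used here gave no condition, time point or replicate number for any of them, so each sample is described by its own values and no groups were compared. Classified reads numbered 82438 in 1CP, 50343 in 2CP, 59219 in 3CP and 58032 in 4A. A genus name was held by 81649, 47627, 57604 and 56970 of these reads, and shares of genera are percentages of those reads unless another base is given. Each sample was 1 library, so there was no replicate error. Intervals are 95% Wilson intervals for shares. Intervals, floors and tests of read counts treat reads as independent, and they cover counting error only. Amplicon reads without molecular identifiers are not independent molecules, so the intervals may be too narrow and the p-values too small. A share of reads is not a share of cells, since 16S gene copy number was not corrected.

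Either Sulfurimonas or Thiobacillus, which both include species that oxidise reduced sulfur with nitrate, was the most abundant genus in each sample. Sulfurimonas, of the Epsilonproteobacteria, held 90.6% of the reads in 1CP (90.4 to 90.8), 3.71% in 2CP (3.54 to 3.88), 1.37% in 3CP (1.28 to 1.47) and 53.4% in 4A (53.0 to 53.8). Thiobacillus, of the Betaproteobacteria, held 27 reads or 0.0331% in 1CP (0.0227 to 0.0481), 47.1% in 2CP (46.7 to 47.6), 82.6% in 3CP (82.3 to 82.9) and 38.2% in 4A (37.8 to 38.6). The medians over the 4 samples were 28.6% for Sulfurimonas and 42.7% for Thiobacillus. Within 1CP, Sulfurimonas reads outnumbered Thiobacillus reads 2741-fold (1880 to 3997). In 4A the same ratio was 1.40 (1.38 to 1.42). Thiobacillus reads outnumbered Sulfurimonas reads 12.7-fold in 2CP (12.1 to 13.3) and 60.4-fold in 3CP (56.3 to 64.8). Together both genera held 90.7% of the reads in 1CP, 50.9% in 2CP, 84.0% in 3CP and 91.6% in 4A.

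**Figure D1:**
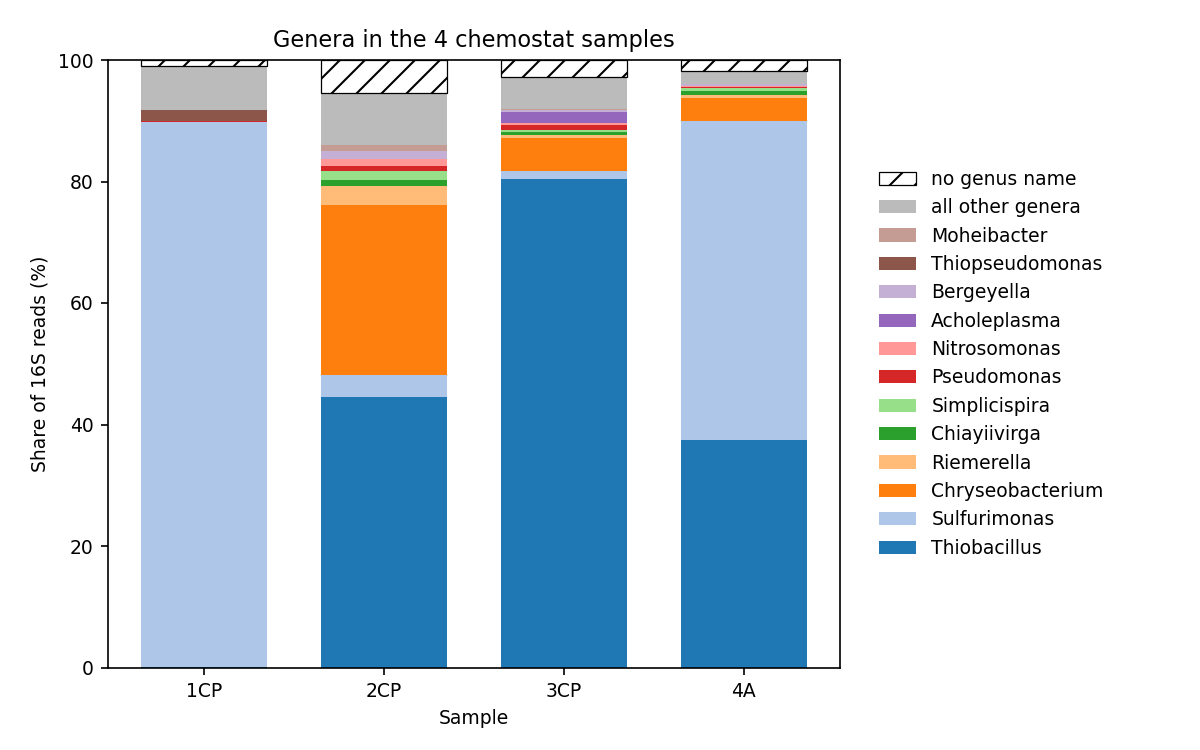
Stacked bars give, for each of the 4 samples, the share of all classified 16S reads (%) in the 12 genera with the highest mean share, in all other genera, and in reads without a genus name. On this base Sulfurimonas held 89.8% in 1CP and 52.5% in 4A, Thiobacillus held 80.4% in 3CP, and Chryseobacterium held 28.0% in 2CP.

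The classes followed these genera. Epsilonproteobacteria held 91.7% of class-named reads in 1CP, 3.62% in 2CP, 1.38% in 3CP and 53.2% in 4A, and Betaproteobacteria held 0.713%, 49.9%, 84.3% and 39.3%. Gammaproteobacteria lay between 1.33% in 4A and 3.41% in 1CP. Alphaproteobacteria reached 1.43% in 2CP and 1.48% in 3CP, against 0.201% in 1CP and 0.236% in 4A. At the phylum level, Proteobacteria took 95.9% of phylum-named reads in 1CP, 57.4% in 2CP, 89.7% in 3CP and 93.8% in 4A.

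The fixed list of sulfur-oxidising, nitrate-reducing genera gave the share of each library that carried the names of its 14 genera. Membership is by genus name, is not a full inventory of such organisms, and no activity was measured. Of these genera, 8 were in the genus table and 6 had a read in any sample. The list held 90.7% of the reads in 1CP (90.5 to 90.9), 50.9% in 2CP (50.4 to 51.3), 84.0% in 3CP (83.7 to 84.3) and 91.7% in 4A (91.4 to 91.9). With Thiopseudomonas, a genus of 1CP that is on no list, the share in 1CP was 92.5%, above that of 4A. In 2CP the list held 48.1% with all classified reads as the base and 49.0% summed from families, so whether it was a majority there depended on the base and level. Almost all of it was Sulfurimonas and Thiobacillus. Sulfurovum followed with 24 reads in 1CP and 7 in 4A. The separate list of other chemotrophic sulfur oxidisers, which leaves out Thioalkalimicrobium at 0.584% in 1CP and Limnobacter at 0.113% in 2CP, held 1.79% in 1CP (1.70 to 1.88), 0.176% in 2CP (0.142 to 0.218), 0.0625% in 3CP (0.0451 to 0.0865) and 0.102% in 4A (0.0788 to 0.132). In 1CP its reads were mainly Arcobacter, at 1.08%, and Halothiobacillus, at 0.594%. Each of these genera held at most 9 reads in any other sample. Thioclava led the list in 2CP with 54 reads. Sulfurospirillum led it in 4A with 43 of 58 reads. That genus also counts among the sulfur reducers left off the reducer list below, so the 4A share is not clearly one of sulfur oxidisers.

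Flavobacteria were most abundant in 2CP. Chryseobacterium, a genus of chemoorganotrophs, held 29.6% of the reads in 2CP (29.2 to 30.1), 5.55% in 3CP (5.36 to 5.74), 3.91% in 4A (3.76 to 4.07) and 23 reads or 0.0282% in 1CP (0.0188 to 0.0423). Riemerella held 3.27% in 2CP, 0.507% in 3CP, 285 reads in 4A and 5 reads in 1CP. Bergeyella held 1.27%, 0.349% and 0.195% in 2CP, 3CP and 4A. No Bergeyella read was found in 1CP, where 0 reads allow up to 0.00367%. Moheibacter held 1.17%, 0.233% and 0.133% in 2CP, 3CP and 4A, with 3 reads in 1CP. Flavobacterium reached 0.661% in 2CP and 0.234% in 3CP and had 1 read in each of 1CP and 4A. Salinirepens held 0.842% in 2CP, 0.0642% in 3CP, 6 reads in 4A and 0 in 1CP. Saccharicrinis, of the Bacteroidia, held 1.41% in 2CP, 0.0677% in 3CP, 0.0343% in 1CP and 2 reads in 4A. The phylum Bacteroidetes held 41.5% of phylum-named reads in 2CP, 8.11% in 3CP, 5.75% in 4A and 0.731% in 1CP, and Flavobacteriia held 39.0%, 7.57%, 5.28% and 0.162% of class-named reads.

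Other genera were abundant in 1 or a few samples. Thiopseudomonas, whose type species oxidises sulfide with nitrate, held 1.81% of the reads in 1CP (1.72 to 1.90) and no read in 2CP, 3CP or 4A. Its share in 1CP was at least 287-fold the share that 0 reads allow in any of those libraries. Geovibrio, an anaerobic genus, held 0.692% in 1CP, 1 read in 2CP and none in 3CP or 4A. Firmicutes held 2.38% of phylum-named reads in 1CP and at most 0.237% elsewhere, and Clostridia held 1.93% of class-named reads in 1CP and at most 0.198% elsewhere. Acholeplasma, a genus of wall-less bacteria, held 1.81% in 3CP (1.70 to 1.92), 31 reads in 4A, 3 in 1CP and 2 in 2CP. It accounted for nearly all of the Tenericutes, which held 1.76% of phylum-named reads in 3CP. Pseudoxanthomonas held 0.734% in 3CP, 0.190% in 4A, 2 reads in 2CP and 0 in 1CP. Chiayiivirga held 1.11% in 2CP, 0.632% in 3CP, 0.649% in 4A and 1 read in 1CP.

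**Figure D2:**
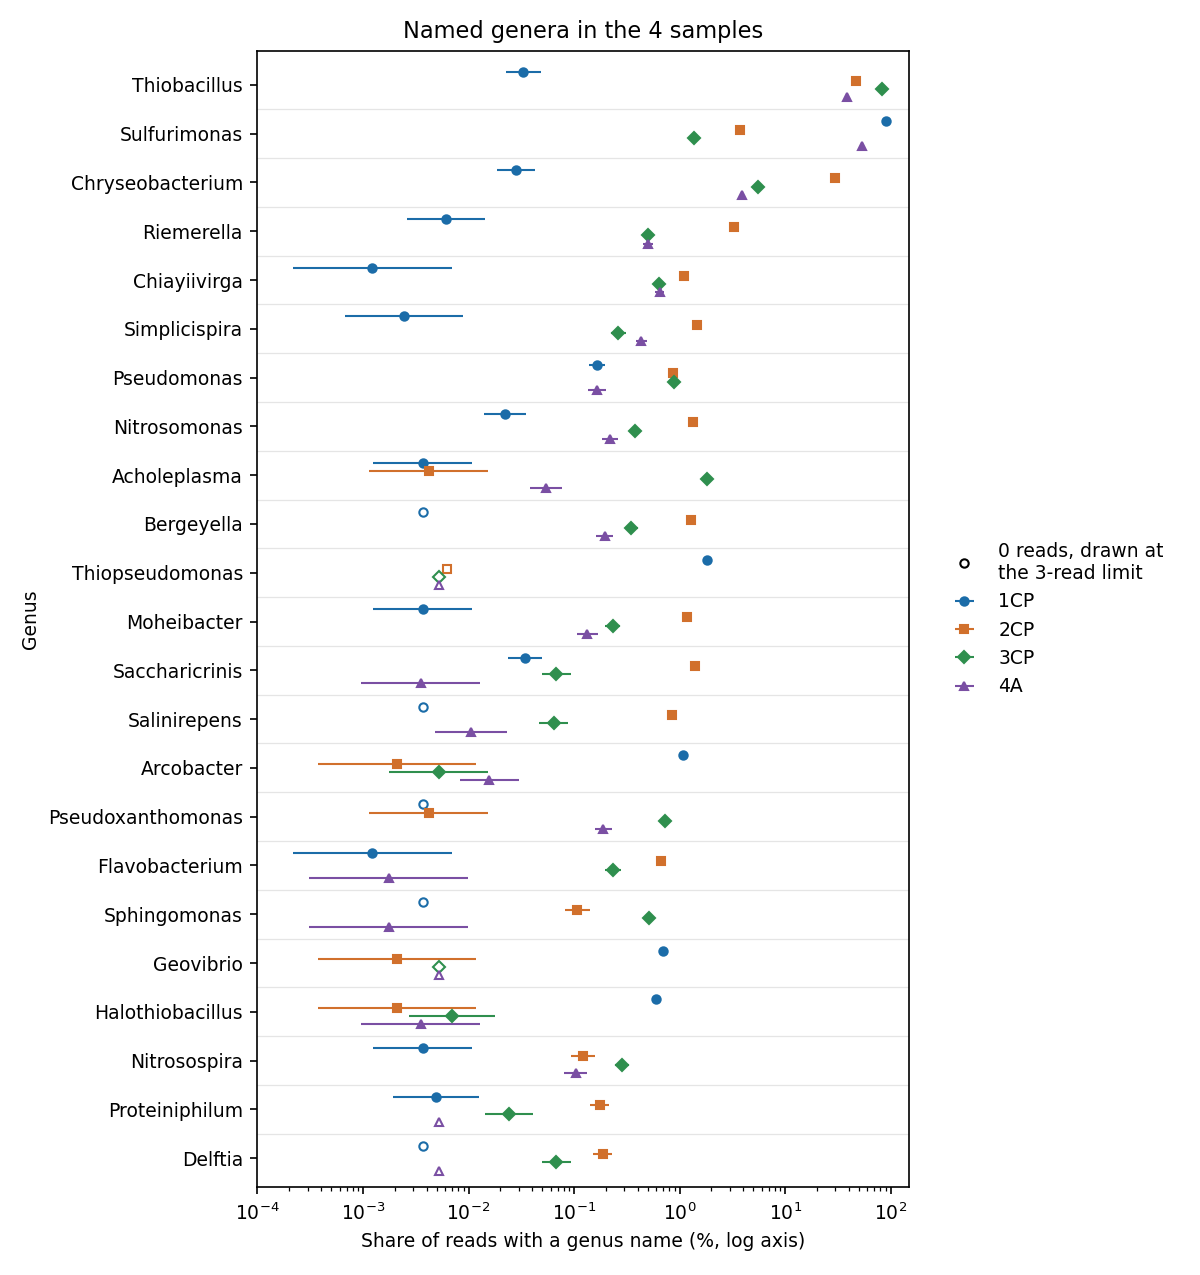
Points give the share of reads with a genus name (%, log axis) of the 23 named genera in each of the 4 samples, with 95% Wilson intervals for counting error and open markers at the 3-read limit where a genus had 0 reads. Chryseobacterium lay at 29.6% in 2CP and 0.0282% in 1CP, and Thiopseudomonas lay at 1.81% in 1CP with 0 reads in the other samples.

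Organotrophic denitrifiers on the fixed list, of which 25 of 30 genera had a read in any sample, held 0.839% of the reads in 1CP (0.779 to 0.904), 3.04% in 2CP (2.89 to 3.20), 2.48% in 3CP (2.36 to 2.61) and 1.11% in 4A (1.02 to 1.20). Thauera led the list in 1CP with 275 reads or 0.337%. Simplicispira led it in 2CP at 1.47% and in 4A at 0.435%, and held 0.262% in 3CP and 2 reads in 1CP. Pseudomonas led it in 3CP at 0.882% and held 0.859% in 2CP, 0.165% in 1CP and 0.165% in 4A. Summed from species names, Pseudomonas held 0.257% in 3CP, below Simplicispira at 0.289%, and 0.698% in 2CP, so its lead in 3CP and its order between these samples depended on the level. Nitrifiers on the fixed list held 22 reads or 0.0269% in 1CP (0.0178 to 0.0408), 1.46% in 2CP (1.36 to 1.58), 0.665% in 3CP (0.602 to 0.735) and 0.323% in 4A (0.280 to 0.373). These were almost all ammonia oxidisers. Nitrosomonas held 1.34% in 2CP, 0.377% in 3CP, 0.219% in 4A and 18 reads in 1CP, and Nitrosospira held 0.122% in 2CP, 0.286% in 3CP, 0.104% in 4A and 3 reads in 1CP. Nitrobacter, a nitrite oxidiser, had 1 read in each of 1CP and 3CP. Of the 10 listed nitrifiers, 4 were rows of the genus table. Nitrospira and Nitrotoga, also listed, were not, so these counts cannot show that nitrite oxidisers were few.

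The fixed list of fermenters held 1.86% of the reads in 3CP (1.75 to 1.97), nearly all of it the Acholeplasma already described, and 0.0784% in 1CP, 0.277% in 2CP and 0.0579% in 4A. Fusibacter at 0.579%, Christensenella at 0.555% and Tissierella at 0.416% of 1CP are anaerobes outside this list, so its low share there is not a share of all fermenting genera. Proteiniphilum led them in 2CP at 0.174%. Genera on the list of sulfate and sulfur reducers, which does not hold Fusibacter, Geovibrio or Sulfurospirillum, had 12 reads in 1CP, 3 in 2CP, 3 in 3CP and 8 in 4A. Listed phototrophic sulfur bacteria had 0, 4, 3 and 1 reads in 1CP, 2CP, 3CP and 4A, and listed predatory genera had 2, 6, 6 and 3. Listed methanogens had 2 reads in 4A, both Methanobrevibacter, and 0 elsewhere. Rows of the genus table covered 12 of 21 listed sulfate and sulfur reducers and 5 of 11 phototrophic sulfur bacteria. They covered 4 of 7 predators and 2 of 12 methanogens, so these low counts do not speak to the other listed genera. None of the 6 anammox genera was a row of the genus table, and 0 reads allow shares of up to 0.00367% in 1CP and 0.00630% in 2CP for a genus that could have been named. Genera on the fixed list of 15 reagent or human-associated names held 0.0135% in 1CP, 0.363% in 2CP, 0.641% in 3CP and 0.0140% in 4A. Sphingomonas gave 297 of the 369 such reads in 3CP, or 0.516% of the library, and Delftia led them in 2CP at 0.187%. Both genera also live in water and soil. The list does not hold Chryseobacterium, Flavobacterium or Pseudomonas, and no blank library was analysed here. Its shares therefore set no limit on reagent reads. Escherichia/Shigella, listed under a joint name that the list did not match, held 58 further reads in 2CP and 0 elsewhere.

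**Figure D3:**
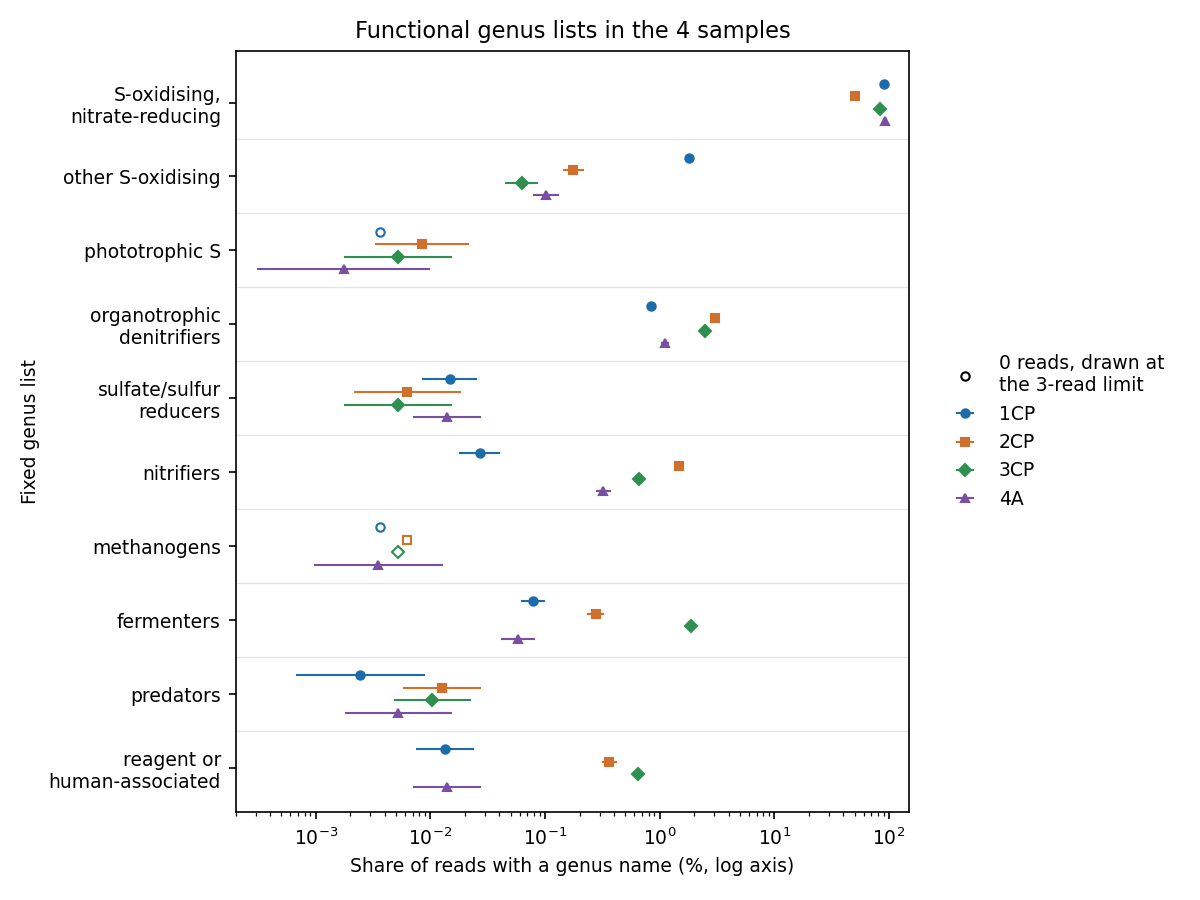
Points give the share of reads with a genus name (%, log axis) of 10 fixed genus lists in each of the 4 samples, with 95% Wilson intervals for counting error and open markers at the 3-read limit where a list had 0 reads. The sulfur-oxidising, nitrate-reducing list lay between 50.9% in 2CP and 91.7% in 4A, and no other list exceeded 3.04%.

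Diversity of genera was lowest in 1CP and highest in 2CP. The Shannon index, in natural-log units with reads lacking a genus name kept as 1 category, was 0.659 in 1CP (0.646 to 0.670 over resampled reads), 1.95 in 2CP (1.93 to 1.97), 1.09 in 3CP (1.07 to 1.11) and 1.20 in 4A (1.19 to 1.21). At an even depth of 47627 reads, 169 genera had a read in 1CP, 298 in 2CP, 267 in 3CP and 192 in 4A. Of 533 genera with a read in any sample, 60 had reads in all 4 samples and 266 had reads in 1 sample only. These counts used all reads of each library and rest mostly on genera with few reads. Under 10 reads were held by 166 of 212 genera in 1CP and 231 of 298 in 2CP. The same held for 226 of 286 genera in 3CP and 172 of 208 in 4A. The 2 leading genera of each sample held 92.5% of its named reads in 1CP, 76.8% in 2CP, 88.2% in 3CP and 91.6% in 4A.

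The libraries of 1CP and 3CP, led by Sulfurimonas and by Thiobacillus, lay farthest apart of the 6 pairs, with a Bray-Curtis dissimilarity of 0.970 (0.969 to 0.972) on a scale from 0 for identical composition to 1 for no shared reads. The value was 0.948 for 1CP and 2CP (0.946 to 0.950), 0.522 for 3CP and 4A (0.519 to 0.527), 0.501 for 2CP and 4A (0.497 to 0.506), 0.459 for 1CP and 4A (0.455 to 0.463) and 0.400 for 2CP and 3CP (0.396 to 0.406). By chi-square tests of the genus counts, every pair of libraries differed by more than the sampling of reads. At these depths repeat libraries of 1 sample could also differ beyond read sampling, so the tests cannot tell whether any samples were repeats. The smallest statistic was 21357 over 102 genera, for 2CP and 3CP, with a Cramér's V of 0.452. These tests compare libraries, not conditions. With the Jaccard measure on presence of a genus in subsamples of even depth, the value for 1CP and 4A was 0.748.

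Species-level names were given to 97.4% of the classified reads in 1CP, 62.9% in 2CP, 84.7% in 3CP and 91.9% in 4A. Sulfurimonas denitrificans took 98.6% of Sulfurimonas reads in 1CP, 98.2% in 2CP, 95.6% in 3CP and 98.3% in 4A. Thiobacillus sajanensis took 96.4%, 94.8% and 96.4% of Thiobacillus reads in 2CP, 3CP and 4A, and Thiobacillus thiophilus took 1.02%, 1.71% and 1.29%. Riemerella columbipharyngis held 2.92% of species-named reads in 2CP, 0.357% in 3CP and 0.385% in 4A. All Chiayiivirga reads in 2CP, 3CP and 4A carried the species-level name Dokdonella sp., so genus and species names of this group differ in the table. By contrast, a species name was held by 0.857% of Chryseobacterium reads in 2CP, 0.626% in 3CP and 0.404% in 4A. Summed from species names, Chryseobacterium therefore held 0.382%, 0.0399% and 0.0169% of the reads in these samples. On the same base Acholeplasma held 0.0139% in 3CP and 0 reads in 4A, and Pseudoxanthomonas held 0.0179% in 3CP and 0.00375% in 4A. Pseudomonas held 0.0488% in 4A. Nitrosospira held 0.0284% in 2CP, 0.0837% in 3CP and 0.0188% in 4A, and Delftia had 0 reads in every sample. In 2CP, where this base was smallest, Chiayiivirga held 1.66%, Moheibacter 1.75% and Salinirepens 1.27%. A species name from a short part of the 16S gene marks the nearest reference name and not an identified species.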

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

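All tests in this part were chosen after the results were seen.

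Reads of the phylum Cyanobacteria/Chloroplast, which belong to no fixed list, exceeded the share that 0 reads allow in 2CP, at 161 reads or 0.320% of classified reads (0.274 to 0.373). In 4A the phylum also exceeded that share, at 42 reads or 0.0724% (0.0536 to 0.0978). That limit is 3 reads and is passed by any taxon with more, so passing it says little. The phylum had 0 reads in 1CP and in 3CP. Of these reads, 156 in 2CP and 41 in 4A were in the class Chloroplast, and 156 in 2CP and 1 in 4A carried the name Streptophyta, the group of land plants and their relatives, whose plastids carry a 16S gene.

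Riemerella, Bergeyella and Moheibacter, all in the same family as Chryseobacterium, had ratios to it that varied less than 1.5-fold across 2CP, 3CP and 4A, the libraries with at least 20 reads of both genera. Other flavobacteria did not follow it. Flavobacterium had 135 reads in 3CP and 1 in 4A, and Salinirepens 37 and 6, against 3195 and 2229 Chryseobacterium reads. One candidate explanation is that the classifier gave a fixed share of Chryseobacterium reads each of the names Riemerella, Bergeyella and Moheibacter. For Moheibacter the ratio was 3.93, 4.19 and 3.41 reads per 100 Chryseobacterium reads, a range of 1.23-fold that sampling of reads covers (chi-square p = 0.363), while the range was 1.40-fold for Riemerella (p = 0.00057) and 1.47-fold for Bergeyella (p = 2.31e-05), beyond the sampling of reads. Of 14 other genera, 0 were as steady as Moheibacter, 1 as steady as Riemerella and 2 as steady as Bergeyella, and in 1CP, with 23 Chryseobacterium reads, exact binomial tests against the pooled ratios gave p = 0.073 for Moheibacter, 0.190 for Riemerella and 0.624 for Bergeyella. The naming explanation stays open for Moheibacter and, with no repeat libraries to give the spread between libraries, for the other 2 genera, and no biological explanation was tested, since the labels give no groups and relatives growing together would show the same steadiness.

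Ammonia oxidisers were named in a sulfide-fed culture, with Nitrosospira at 0.258, 0.347 and 0.271 reads per 100 Thiobacillus reads in 2CP, 3CP and 4A, the libraries with at least 20 reads of both genera. If Nitrosospira were a misread fixed share of Thiobacillus, also a betaproteobacterium, this ratio would not vary beyond sampling. It varied 1.34-fold (chi-square p = 0.0792), and none of 14 other genera followed Thiobacillus as closely. In 1CP, however, there were 3 Nitrosospira reads with 27 Thiobacillus reads. The pooled share of Nitrosospira among the reads of both genera gives 0.0919 expected reads there (exact binomial p = 0.00011). The 1CP reads go against a fixed share, but they are 3 reads of 1 library, so the explanation stays open for the other libraries. The Nitrosomonas ratio varied 6.23-fold (p = 3.34e-187), which argues against the same explanation for Nitrosomonas, and no biological explanation was tested.

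The 1767 Sulfurimonas reads in 2CP, the 788 in 3CP and the 27 Thiobacillus reads in 1CP could be reads carried between libraries, in which case a source's other genera would arrive at the same rate. Libraries other than these 4 could not be examined as sources. Reads of 1CP carried into 2CP as the source of its Sulfurimonas would bring 10 genera at 5 or more reads, and all 10 lay below their expected number, 8 of them past an exact binomial test with Bonferroni correction. For reads of 1CP carried into 3CP, all 6 such genera lay below, 4 of them past that test, with 7 reads seen against 46.4 expected, so 1CP was not the source of all these Sulfurimonas reads. Reads of 2CP carried into 1CP stay open for its Thiobacillus reads, since Chryseobacterium, the 1 genus tested, had 23 reads against 17.0 expected, and reads of 3CP carried into 1CP gave 0 testable genera. For reads of 4A carried into 2CP, 0 of 10 genera passed the test, with Pseudoxanthomonas at 2 reads against 6.27 expected (one-sided p = 0.0556 before correction) but the other 9, and all 5 genera for 4A into 3CP (also 0 past the test), were so abundant in the receiving sample that they had no chance to fall below, so the test decided nothing about 4A as a source.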

How the results depend on the processing

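Using all classified reads as the base of shares, adding Thiopseudomonas to the list, and every alternative for named genera other than Thiobacillus, were chosen after the data were seen. The labels used here name no replicates to leave out, and no paired analysis was possible because the labels give no groups. A value was counted as moved where it left its own counting interval, which at these depths is narrow, so small moves count. Subsampling to the shallowest sample moved none of the 4 Shannon and 6 Bray-Curtis values, and genera with at least 10 reads moved none of the 6 Bray-Curtis values. The base of reads with a genus name only equals the reported base and moved nothing.

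The share of sulfur-oxidising, nitrate-reducing genera became 92.5% in 1CP with Thiopseudomonas added. The wider list, which adds the other chemotrophic sulfur oxidisers and Paracoccus, held 92.6% in 1CP. It therefore also counts genera that are not listed as both sulfur-oxidising and nitrate-reducing. Each of these changes put 1CP above 4A. At the family level the share was 49.0% in 2CP, 82.7% in 3CP and 91.2% in 4A. At the species level it was 91.7% in 1CP, 74.7% in 2CP, 93.1% in 3CP and 96.6% in 4A, which put 3CP above 1CP. With genera of at least 10 reads it was 90.9% in 1CP, 84.4% in 3CP and 91.9% in 4A. With all classified reads as the base it was 89.8%, 48.1%, 81.7% and 90.0% in 1CP, 2CP, 3CP and 4A. It was lowest in 2CP under each of these.

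Thiobacillus, which led by the mean share over the 4 samples but lay below Sulfurimonas in 1CP and 4A, held 69.2% in 2CP, 91.6% in 3CP and 39.9% in 4A at the species level, 83.1% in 3CP with genera of at least 10 reads, and 44.6%, 80.4% and 37.5% in 2CP, 3CP and 4A with all classified reads as the base. In 2CP the species level lost 15954 genus-named reads, 87.7% of them Chryseobacterium, which raises by construction the share of any genus there that kept its reads. The order of samples by Thiobacillus share did not change under these alternatives.

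Shannon diversity in 1CP, 2CP, 3CP and 4A became 0.611, 1.84, 0.994 and 1.13 with unnamed reads left out, 0.632, 1.90, 1.04 and 1.17 with genera of at least 10 reads, 0.627, 1.56, 0.983 and 1.13 at the family level, and 0.701, 1.73, 1.01 and 1.18 at the species level. The order of samples did not change.

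Bray-Curtis dissimilarity with unnamed reads left out was 0.955 for 1CP and 2CP, 0.979 for 1CP and 3CP, 0.508 for 2CP and 4A and 0.532 for 3CP and 4A. For the pairs 1CP-2CP, 1CP-3CP, 1CP-4A, 2CP-3CP, 2CP-4A and 3CP-4A it was 0.933, 0.956, 0.453, 0.392, 0.493 and 0.516 at the family level, 0.936, 0.958, 0.451, 0.357, 0.492 and 0.516 at the species level, and 0.784, 0.784, 0.597, 0.367, 0.479 and 0.423 with square roots of the shares. Jaccard values in that order, for subsamples of even depth, were 0.768, 0.776, 0.748, 0.569, 0.665 and 0.654. Square roots and the Jaccard measure changed the order of pairs, but 2CP-3CP was lowest under every alternative run. The highest pair was 1CP-3CP, except that with square roots it could not be ranked against 1CP-2CP, as both were 0.784. Except where the construction of an alternative shows it, the cause was not tested.

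Of the 88 shares of other named genera, the species level moved 42, all classified reads as the base moved 5, and genera of at least 10 reads moved 1. Depth limits genera with few reads: Arcobacter, Halothiobacillus and Geovibrio outside 1CP rest on 0 to 9 reads.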

Other observations

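The genera described in this part were chosen after their values were seen.

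1CP held a set of genera that were almost absent from the other samples. With a threshold of 0.1% in a sample and at most 3 reads in each of the others, 8 genera belonged to 1CP and held 5.03% of its reads. Besides Thiopseudomonas and Geovibrio these were Thioalkalimicrobium, a sulfur oxidiser described from soda lakes, at 0.584% (0.534 to 0.639), Fusibacter, an anaerobe with species that reduce thiosulfate, at 0.579% (0.530 to 0.634), Christensenella at 0.555% (0.506 to 0.608), Tissierella at 0.416% (0.375 to 0.463), Erysipelothrix at 0.273% (0.240 to 0.311) and Castellaniella, a genus with denitrifying species, at 0.118% (0.0963 to 0.144). None of these 6 had more than 2 reads in any other sample. Fusibacter, Christensenella, Tissierella and Erysipelothrix are Firmicutes, the phylum that reached 2.38% of phylum-named reads in 1CP.

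The same threshold gave 5 genera for 2CP, which held 0.855% of its reads, 0 for 3CP and 1 for 4A. In 2CP they were Streptophyta at 0.328%, the Parcubacteria group at 0.166%, Luedemannella at 0.126%, Escherichia/Shigella at 0.122% and Limnobacter, a genus with thiosulfate-oxidising species, at 0.113%. In 4A the genus was Thermomonas, at 62 reads or 0.109% (0.0849 to 0.139).

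Among genera on the organotrophic denitrifier list but outside the naming rule, some differed between samples. Membership is by genus name, and Paracoccus is also counted in the wider list of sulfur oxidisers. Azoarcus held 0.174% in 3CP, 0.0777% in 2CP, 0.0386% in 4A and 2 reads in 1CP. Aquamicrobium held 0.208% in 2CP, 0.115% in 3CP, 12 reads in 4A and 0 in 1CP. Hydrogenophaga held 0.174% in 2CP and at most 19 reads elsewhere. Paracoccus held 0.132% in 1CP, 20 reads in 2CP, 21 in 3CP and 1 in 4A. Stenotrophomonas was more even outside 1CP, at 0.0630% in 2CP, 0.0677% in 3CP and 0.0579% in 4A, with 2 reads in 1CP.

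Reads with a genus name and no species name were mostly Chryseobacterium in 2CP, at 87.7% of 15954 reads (87.2 to 88.2), and in 4A, at 60.7% of 3660. In 3CP the share was 42.8% of 7416. In 1CP the leading genus among 1372 such reads was Sulfurimonas, at 31.3%.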
